A study of Drosophila melanogaster with 48 samples.

How the data were processed

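S2 and S3 cells were transfected with 2 ug of dsRNA against Csl4, Rrp40, Rrp6 or GFP, and RNA was taken 5 days later, per the labels' protocols. Poly(A)+ and RiboMinus libraries were sequenced, and ChIP-seq was done for Rrp6, Rrp40 and Su(Hw) with an input after 10 min in 1% formaldehyde, 48 samples in all. The deposited files are 12 tables of gene comparisons and 6 peak lists. Reads passed through CASAVA 1.8, cutadapt 1.0, TopHat 1.4.1, HTSeq 0.5.3p9 and DESeq 1.9.11, per the submitters' processing notes. Of the 12 tables, 8 compare 2 libraries with 2 and 4 compare 1 with 1 (Rrp40 in S2 poly(A) RNA and the S2 RiboMinus tables), and DESeq used a local fit, with dispersions per condition or, for 1 against 1, blind to the condition, per the file headers.

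The signal columns of the deposited tables are mean counts per group after the authors divided each library by its DESeq size factor. The fold columns are the ratio of the knockdown mean to the GFP mean, made by the authors before they deposited the tables. The log2 columns hold the binary logarithm of that ratio as deposited by the authors, infinite where a mean is 0. The p-value columns hold the p-value of the authors' DESeq test and the same adjusted over genes, as deposited. The peak lists are intervals on the dm3 build from reads aligned with Bowtie 0.12.7 and treated with Picard, per the submitters' processing notes, and carry no score. Technical replicates were pooled for Rrp6 and Rrp40, Su(Hw) has 1 sample per line, and the peak caller is not given in the sources used here.

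The files were expected to hold either counts or the authors' comparisons, and they hold the latter. Each mean is a sum of whole reads over size factors, so the reads of each library were worked back from the means, which gave all 15070 values or 15068 of them (99.99%) in each group, for 28 libraries. On simulated data the method returned 15000 of 15000 values at each of 4 ratios of depth (3, 10, 50 and 130). The 5 HTSeq summary values of each table stayed out of library sizes and tests, and the share of the mean total that the unassigned and the ambiguously aligned reads hold is 79.9 to 91.4%. The tables hold 15065 gene IDs, of which 14085 were matched to a symbol and 980 were not. Library depths on the decoded genes, in reads, were 8248223 and 939776 for GFP replicates 1 and 3 in S2 poly(A) RNA, 8378647 and 532934 for Csl4, 1457393 for Rrp40 and 5737608 and 777607 for Rrp6. In S3 poly(A) RNA they were 5568743, 69426568 and 984832 for GFP replicates 1, 2 and 3, 3055056 and 1451054 for Csl4, 54977201 and 602269 for Rrp40, and 5776164 and 1055174 for Rrp6. In S3 RiboMinus RNA the deeper libraries held 6217631 (GFP), 7971123 (Csl4), 9212060 (Rrp40) and 7365965 (Rrp6) reads and the shallower ones 138219, 133439, 108782 and 114733. The S2 RiboMinus libraries held 67743 (GFP), 76535 (Csl4), 157282 (Rrp40) and 70460 (Rrp6). Libraries of a group therefore differ in depth widely, and genes with few reads rest on the deeper library alone.

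A gene counts as called in the authors' deposited tables at an adjusted p of at most 0.05. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM scaling, default filter on low counts, Benjamini-Hochberg adjustment over genes, R 4.3.3) was fitted once per line and fraction with the knockdown and, as a block, the depth class of the library (deeper or shallower). The only Rrp40 library of S2 poly(A) RNA entered as shallower by its replicate number, 3, which the shallower GFP library shares. Standard errors are the absolute log2 change over the square root of F. In the S3 RiboMinus set the prior degrees of freedom were infinite, so every gene has the same quasi-dispersion there. The block was chosen after the numbers of calls with and without it had been seen. Differences between deeper and shallower libraries correlated across groups. The correlation ran from 0.68 to 0.71 in S2 poly(A), 0.36 to 0.66 in S3 poly(A) and 0.28 to 0.39 in S3 RiboMinus RNA. The level that low counts in the shallower libraries alone would give was not simulated. The fits were tested on simulated data of the Rrp6 comparisons with 200 changed genes. They returned 38.8, 89.6 and 100% of 2-, 4- and 8-fold changes in S2 poly(A) RNA. The shares were 20.9, 77.6 and 97.0% in S3 poly(A) and 23.9, 82.1 and 100% in S3 RiboMinus RNA. False calls were 10, 12 and 20, a larger share of the calls than 0.05 in each set. Dispersions came from the fit with the block and no deviation by depth was simulated, so the block itself was not tested. DESeq2 1.42.0 with its own size factors, edgeR without the block, without the filter, with RLE scaling, on a knockdown's own libraries and without each library in turn are the alternatives. Interaction terms between lines and between fractions were tested in joint edgeR fits.

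Named genes follow a rule set before the data were examined. It takes the targeted genes in each table, and the 5 highest and 5 lowest called genes per table with a mean count of at least 100. It adds up to 10 genes per direction called in both lines' poly(A) tables of a knockdown, genes called in all poly(A) tables of a line, and up to 4 called members per list and table with a mean of at least 20. List members outside the rule were chosen after their values were seen. The 12 gene lists of the report are cell cycle genes, cytosolic ribosomal proteins, insulator proteins, exosome core genes with Rrp6, JAK-STAT and stress humoral genes, apoptosis and DNA damage genes, heat shock genes, neuronal genes, snRNAs, snoRNAs, genes with CR symbols and tRNAs. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, adjusted over lists. Each list's median in the authors' deposited tables was also ranked among 10000 random lists of the same size matched in 10 bins of mean expression, with percentiles under 2.5 or over 97.5 taken as outside.

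Overlaps of calls were tested with the two-sided Fisher test. In 20 simulations of unchanged knockdown groups against shared GFP libraries, the correlation and covariance were those that sharing alone makes. Peak overlap of at least 1 bp was set against 1000 circular shifts within chromosome arms, one-sided, adjusted over 15 pairs. Intervals are 95% binomial. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Other columns of per-sample values were absent. Promoter results were left out, since no annotation of the dm3 build was at hand, and gene names came from tables that pair IDs and symbols. Reads of the ChIP-seq samples were not analysed here.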

Results

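Drosophila S2 and S3 cells had received dsRNA against Rrp6, Rrp40 or Csl4, subunits of the exosome that trims and degrades RNA, or against GFP, and poly(A)+ and RiboMinus RNA was sequenced 5 days later. Rrp6, Rrp40 and the insulator protein Su(Hw) were mapped by ChIP-seq in both lines. Changes are log2 ratios of the libraries labelled knockdown to those labelled GFP, ± SE, from edgeR quasi-likelihood fits with a block for sequencing depth on the recovered reads, unless the authors' deposited table is named. Each such value rests on 2 knockdown libraries (1 for Rrp40 in S2 poly(A) RNA, whose SE and p borrow the spread of the other groups) and on 2 GFP libraries, or 3 in S3 poly(A) RNA. Whether replicates came from separate cultures is not given in the sources used here. With the depth block, p-values measure the spread between these samples that is left after the common deeper-shallower difference is removed. They also borrow spread across genes, and in S3 RiboMinus RNA every gene has the same quasi-dispersion. The comparisons, the threshold of 0.05 on the adjusted p, the gene lists and the rule for naming genes were set before the data were examined. The edgeR fits were chosen after the files had been seen, and the depth block after the numbers of called genes with and without it had been seen, so the counts without it are given beside.

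Reads of the targeted gene were more numerous, not fewer, in the libraries labelled as its knockdown. Rrp6, the nuclear exosome's distributive exonuclease, rose by 3.45 ± 0.34 in S2 poly(A), 4.97 ± 1.07 in S3 poly(A) and 8.63 ± 0.40 in S3 RiboMinus RNA (edgeR adjusted p 1.1e-07, 0.00633 and 1.4e-96). Rrp40, an RNA-binding subunit of the exosome's cap, rose by 4.83 ± 0.25 in S2 poly(A) RNA (1 library, assumed to vary like the other groups) and 7.56 ± 0.40 in S3 RiboMinus RNA (edgeR adjusted p 1.8e-11 and 3.1e-75). Csl4, another cap subunit, rose by 7.90 ± 0.39 in S3 RiboMinus RNA (edgeR adjusted p 2.4e-87). In S3 poly(A) RNA the excess sat in the shallower library: 182-fold for Csl4, 401-fold for Rrp40 and 148-fold for Rrp6 in reads scaled to library depth, against 5.20-fold, 1.56-fold and 3.08-fold in the deeper one. Leaving out 1 library at a time moved the change of Rrp6 there from 1.36 to 6.71, and edgeR's adjusted p was 0.0954 for Csl4 (5.72 ± 1.14) and 0.371 for Rrp40 (6.59 ± 1.66). Csl4 in S2 poly(A) RNA was 2.83-fold in the deeper and 0.479-fold in the shallower library (0.69 ± 0.36, edgeR adjusted p 0.455). The single S2 RiboMinus libraries held 12934 reads of Rrp6 against 7 under GFP dsRNA, 40378 of Rrp40 against 24, and 1668 of Csl4 against 0, without a test of spread. In the authors' deposited tables, the gene was higher in 12 of the 12 tables of its own knockdown and passed the DESeq threshold in 5. Reads of the gene were over 10-fold higher, with at least 10 of them, in 11 of those 12 tables and in 0 of the 24 pairings of a targeted gene with another knockdown. Eno, an enolase gene that overlaps Rrp40 on the genome, rose by 1.34 ± 0.24 in S2 poly(A) and 4.17 ± 0.33 in S3 RiboMinus RNA labelled Rrp40 knockdown (edgeR adjusted p 0.0165 and 1.8e-32). Whether reads were counted by strand is not given in the sources used here, so its change is uncertain. Rrp40 fell in S2 poly(A) libraries labelled Rrp6 knockdown (-0.87 ± 0.21, edgeR adjusted p 0.00249). The labels state that the knockdowns were checked by Western blot, and blot values are not given in the sources used here. Reads of the targets thus do not show the knockdowns, and they may include reads of the transfected dsRNA. Libraries are therefore called by their labels throughout. EdgeR loses the call of Eno in S3 RiboMinus RNA labelled Rrp40 knockdown without the deeper GFP library. It also drops Rrp40 in S2 poly(A) RNA labelled Rrp6 knockdown without the deeper Rrp6 library.

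**Figure D1:**
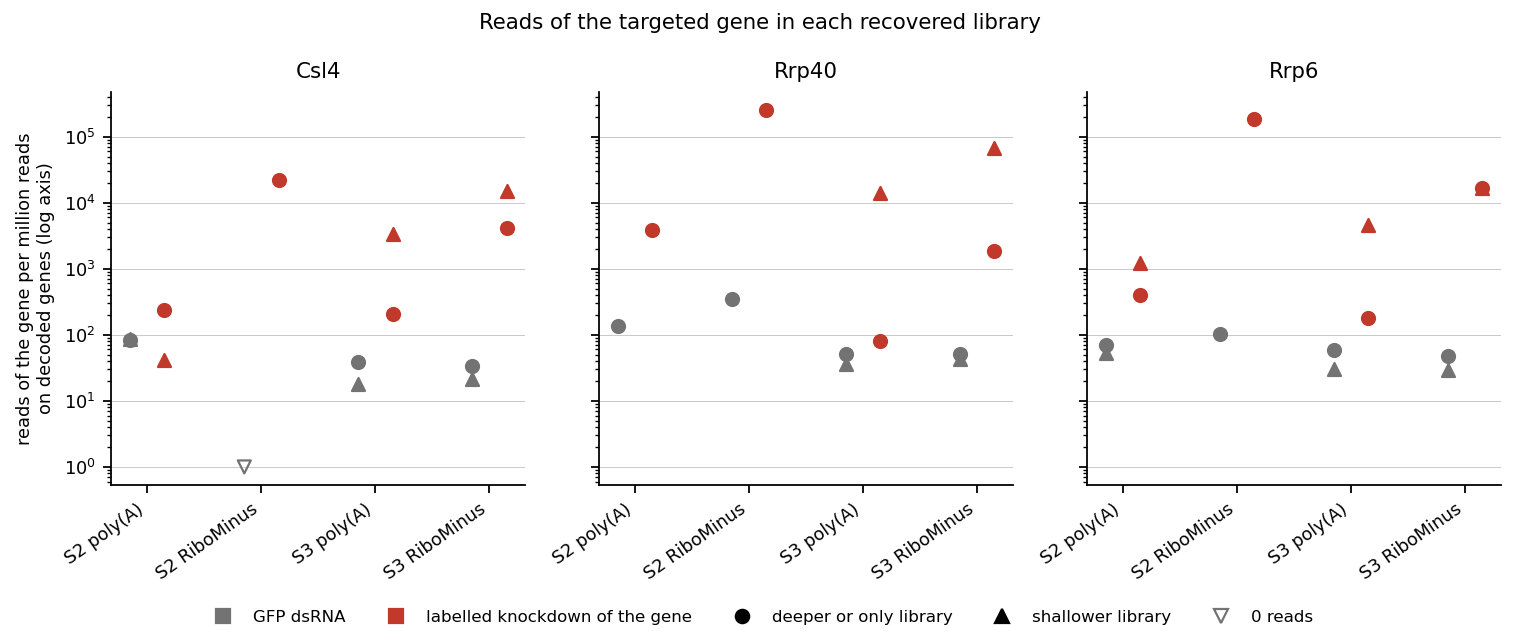
Reads of Csl4, Rrp40 and Rrp6, scaled to the reads on decoded genes, in each library labelled as the gene's knockdown (red) and in the GFP libraries (grey). Rrp6 in the deeper S3 RiboMinus library held 122238 reads, a depth-scaled ratio to GFP of 343.

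In poly(A) RNA of the libraries labelled Rrp6 knockdown, genes rose and fell in both lines. Cyp6d2, a cytochrome P450 gene, rose by 5.69 ± 0.31 in S2 and 4.68 ± 0.54 in S3, CG8620 by 5.65 ± 0.32 in S2 and 6.55 ± 0.59 in S3, and IRSp53, whose product links membranes to actin, by 5.52 ± 0.29 in S2 and 4.82 ± 0.57 in S3. Mdr49, an ABC drug transporter gene, rose by 4.67 ± 0.33 in S2 and 5.43 ± 0.44 in S3, and Ir40a, an ionotropic receptor gene, by 4.08 ± 0.30 in S2 and 4.54 ± 0.34 in S3. The stress regulator p53 rose by 2.70 ± 0.23 in S2 and 3.60 ± 0.46 in S3, and Arc1, which encodes a capsid-like RNA carrier, by 3.90 ± 0.22 in S2 and 4.64 ± 0.37 in S3. Genes that fell in both lines included kuk, a nuclear envelope gene (-2.89 ± 0.28 in S2 and -2.05 ± 0.33 in S3), Tina-1 (-2.66 ± 0.28 in S2 and -2.16 ± 0.22 in S3) and Ts, the thymidylate synthase gene (-2.69 ± 0.25 in S2 and -3.15 ± 0.27 in S3). EdgeR's adjusted p for these 10 genes ran from 2.1e-11 (Cyp6d2) to 2.6e-07 (Tina-1) in S2 and from 8.7e-05 (Arc1) to 0.00165 (kuk) in S3. With the depth block, edgeR called 1598 genes higher and 1335 lower of 7905 in S2, and 1562 higher and 1297 lower of 7923 in S3. Without the block it called 9 higher and 0 lower in S2, with 1392 genes at an unadjusted p under 0.05, and 664 higher and 412 lower in S3, with 2442. DESeq2 with the block called 1112 and 754 in S2 and 1765 and 1314 in S3. On the libraries of this knockdown and its GFP controls alone, edgeR with the block called 1642 and 1380 in S2 and 518 and 267 in S3. Single libraries moved these totals: 2933 calls in S2 became 1169 without the deeper Rrp6 library and 1634 without GFP replicate 1. In S3 2859 became 1149 without the deeper Rrp6 library, 1659 without GFP replicate 1 and 1661 without GFP replicate 2. In the authors' deposited tables, DESeq passed 53 genes higher and 4 lower of 12347 in S2, and 247 higher and 41 lower of 11779 in S3. The 4 lower genes in S2 in the authors' deposited table were kuk, Tina-1, CG33307 and CG31231. CG31231 rests on 1 library, with 786 reads in GFP replicate 3 against 6 in GFP replicate 1.

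**Figure D2:**
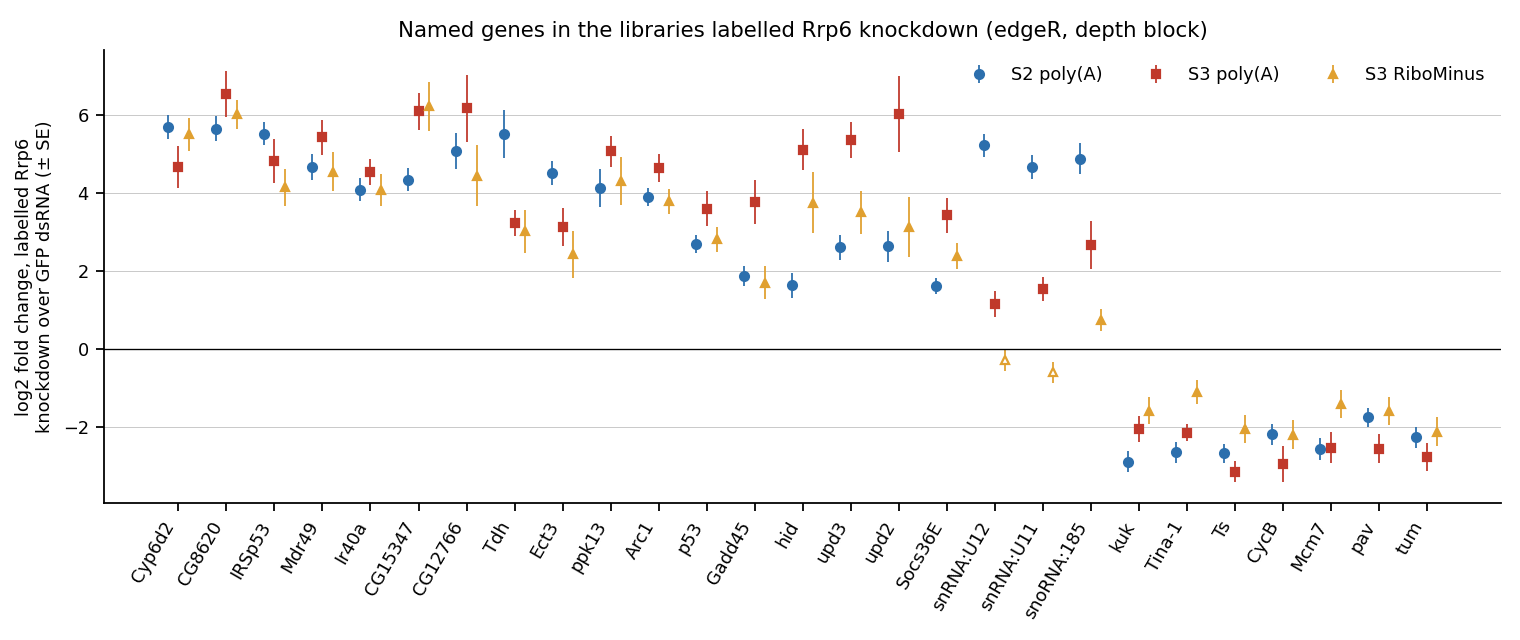
Log2 fold changes ± SE in the libraries labelled Rrp6 knockdown, with open symbols where edgeR's adjusted p is above 0.05; Cyp6d2 changed by 5.69, 4.68 and 5.51 and CycB by -2.19, -2.96 and -2.20 in S2 poly(A), S3 poly(A) and S3 RiboMinus RNA. Without the deeper Rrp6 library, upd2 in S3 poly(A) RNA no longer passed.

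Cell cycle genes and, mainly in S3, ribosomal protein genes fell in the libraries labelled Rrp6 knockdown. CycB, the mitotic cyclin, changed by -2.19 ± 0.27, -2.96 ± 0.46 and -2.20 ± 0.37 in S2 poly(A), S3 poly(A) and S3 RiboMinus RNA, Mcm7 of the replicative helicase by -2.57 ± 0.28, -2.54 ± 0.40 and -1.42 ± 0.37, and tum, a cytokinesis gene, by -2.27 ± 0.27, -2.78 ± 0.35 and -2.12 ± 0.38. Of 30 cell cycle genes tested, 22, 20 and 14 fell (23, 21 and 16 adjusted over the list alone), and 1 rose in each, CycG (1.37 ± 0.22, 1.08 ± 0.25 and 1.20 ± 0.27), with medians of -1.36, -1.51 and -1.14. Camera with a preset correlation of 0.01 gave the list an adjusted p of 9.2e-11, 7.5e-08 and 3.1e-05, and an adjusted p of 0.391, 0.724 and 0.699 with the correlation estimated. Of ribosomal protein genes 72 of 79 fell in S3 poly(A) and 58 of 79 in S3 RiboMinus RNA, against 18 of 80 in S2 poly(A) RNA (76, 69 and 17 adjusted over the list alone), with medians of -1.36, -0.92 and -0.18. RpS2 changed by -2.14 ± 0.26 in S3 poly(A), -1.32 ± 0.28 in S3 RiboMinus and -0.85 ± 0.18 in S2 poly(A) RNA, and RpL36 by -1.79 ± 0.25 and -1.34 ± 0.28 in S3, with -0.16 ± 0.17 in S2 (edgeR adjusted p 0.498). Camera gave them an adjusted p of 2.8e-22, 2.7e-26 and 0.0109 in the same order, and 0.724, 0.394 and 0.391 with the correlation estimated. DESeq2 called 20, 20 and 6 cell cycle genes lower in S2 poly(A), S3 poly(A) and S3 RiboMinus RNA, and 14, 75 and 46 ribosomal protein genes. Without the depth block edgeR called 15 cell cycle genes lower in S3 poly(A) RNA and otherwise 0 members of either list lower, while 13, 9 and 0 cell cycle genes and 3, 41 and 13 ribosomal protein genes, in that order, were lower in every fit that left out 1 library. Counts over every fit that left out 1 library take, here and below, each gene's direction from the fit of all libraries. A gene with too few reads to be tested in 1 of these fits counts as not passing. In S3 RiboMinus RNA such counts therefore mix genes that lost the call with genes that were not tested. EdgeR loses the call of CycG in S3 poly(A) RNA labelled Rrp6 knockdown without the deeper Rrp6 library. It also drops CycB and RpS2 in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library. In S3 RiboMinus RNA the calls of CycG, Mcm7 and tum end without the deeper GFP library or the deeper Rrp6 library.

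Genes of the JAK-STAT list rose as well. The cytokine gene upd3 rose by 2.61 ± 0.31, 5.37 ± 0.46 and 3.50 ± 0.56 in S2 poly(A), S3 poly(A) and S3 RiboMinus RNA, and Socs36E, the pathway's feedback inhibitor, by 1.62 ± 0.20, 3.43 ± 0.45 and 2.38 ± 0.34. With upd2 and vir-1 these make 4 of 7 tested genes in each set (4, 5 and 4 adjusted over the list alone). The adjusted p from camera was 0.0155, 0.00646 and 0.00911, and 0.396, 0.481 and 0.667 with the correlation estimated. The cell death gene hid rose by 1.63 ± 0.31, 5.11 ± 0.53 and 3.76 ± 0.78, and the repair genes Ku80 and PolZ1 by 1.70 ± 0.24, 1.66 ± 0.24 and 1.35 ± 0.36 and by 1.57 ± 0.27, 1.89 ± 0.43 and 1.84 ± 0.32. Of 16 apoptosis and DNA damage genes, 7, 8 and 6 rose and 2, 0 and 0 fell (7, 9 and 6 up and 2, 1 and 0 down adjusted over the list alone). By camera the list had an adjusted p of 0.0646, 0.00875 and 0.0714, and of 0.563, 0.778 and 0.699 with the correlation estimated. Of the heat shock genes, 6 of 9 rose in S2 poly(A) RNA, among them Hsp26 (1.15 ± 0.22), against 2 higher and 1 lower of 10 in S3 poly(A) and 2 lower of 10 in S3 RiboMinus RNA (6, then 3 and 1, then 2 adjusted over the list alone). Camera gave these an adjusted p of 0.0155, 0.981 and 0.144, and of 0.563, 0.992 and 0.699 with the correlation estimated. Hsp60A, the mitochondrial chaperone, is the lower one in S3 poly(A) RNA (-1.25 ± 0.31). The synaptic active zone gene brp rose by 2.11 ± 0.24, 3.54 ± 0.72 and 1.84 ± 0.68. Neuronal genes rose without a falling member: 5 of 8, 3 of 7 and 4 of 8 (5, 3 and 7 adjusted over the list alone). The adjusted p from camera was 0.00773, 0.051 and 0.00215, and 0.391, 0.778 and 0.699 with the correlation estimated. Without the depth block edgeR called 0, 3 and 0 JAK-STAT genes, 0, 5 and 0 apoptosis and DNA damage genes, 0 heat shock genes and 0, 1 and 0 neuronal genes higher. DESeq2 called 4, 5 and 3, then 7, 8 and 4, then 5, 1 and 0, and then 5, 3 and 1 higher. In every fit that left out 1 library, 2, 3 and 1 JAK-STAT genes, 5, 4 and 1 apoptosis and DNA damage genes, 3, 0 and 0 heat shock genes and 3, 2 and 0 neuronal genes were higher. EdgeR no longer calls PolZ1 in S3 poly(A) RNA labelled Rrp6 knockdown without the deeper Rrp6 library. It also drops PolZ1 and upd3 in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library. The call of Ku80 there ends without the deeper GFP library or the deeper Rrp6 library, that of brp without the shallower GFP library. For S3 RiboMinus RNA labelled Rrp6 knockdown, too few reads were left to test brp and hid without the deeper GFP library, and brp, hid and upd3 without the deeper Rrp6 library.

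Insulator protein genes fell in S2 poly(A) RNA labelled Rrp6 knockdown. The gene su(Hw) itself changed by -1.49 ± 0.25 in S2 poly(A) and -0.88 ± 0.29 in S3 poly(A) RNA, Cp190 by -1.19 ± 0.22 and -0.36 ± 0.22, the latter not past the threshold (edgeR adjusted p 0.212), and Ibf2 by -1.91 ± 0.25 and -1.45 ± 0.28. Of the list, 7 of 12 genes fell in S2, 3 of 13 fell and 1 rose in S3 poly(A) RNA, and 1 of 13 fell in S3 RiboMinus RNA (7, then 3 and 1, then 0 adjusted over the list alone). By camera the list had an adjusted p of 0.00242, 0.557 and 0.22, and of 0.391, 0.778 and 0.699 with the correlation estimated. Among 10 exosome core genes, Rrp4 (-0.62 ± 0.20), Rrp46 (-1.06 ± 0.27), Ski6 (-0.73 ± 0.24) and Rrp40 fell in S2 poly(A) RNA while Rrp6 rose. Only Rrp6 of these 10 passed in S3 poly(A) RNA, and in S3 RiboMinus RNA Rrp6 and Csl4 rose and Rrp4 fell (-1.09 ± 0.41). Adjusted over the list alone 1 rose and 5 fell, 1 and 0, and 2 and 2 in the same order (camera adjusted p 0.224, 0.338 and 0.863, and 0.572, 0.778 and 0.938 with the correlation estimated). Without the depth block edgeR called 0 insulator genes in S2 and in S3 RiboMinus RNA; DESeq2 called 7, 3 and 0 lower, and 4, 0 and 0 were lower in every fit that left out 1 library. EdgeR loses the call of Rrp4 in S2 poly(A) RNA labelled Rrp6 knockdown when any 1 library is left out. The call of Rrp46 ends without GFP replicate 1 or the deeper Rrp6 library, that of Ski6 without GFP replicate 3, the deeper Rrp6 library or the shallower Rrp6 library. It also drops su(Hw) in S3 poly(A) RNA labelled Rrp6 knockdown without GFP replicate 1, GFP replicate 2 or the deeper Rrp6 library. The call of Ibf2 there ends without the deeper Rrp6 library. It further drops Rrp4 in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library, the deeper Rrp6 library or the shallower Rrp6 library.

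Small nuclear RNAs, some of the minor spliceosome among them, rose in S2 poly(A) RNA labelled Rrp6 knockdown. snRNA:U12 rose by 5.23 ± 0.29, snRNA:U11 by 4.66 ± 0.31 and snRNA:U6atac by 4.62 ± 0.37, against 1.14 ± 0.34, 1.54 ± 0.30 and 2.35 ± 0.62 in S3 poly(A) RNA. In S3 RiboMinus RNA the same RNAs were at -0.29 ± 0.28, -0.60 ± 0.28 and 0.37 ± 0.27, none past the threshold (edgeR adjusted p 0.523, 0.11 and 0.388). Of the snRNAs tested 7 of 9 rose, 4 of 7 rose and 3 of 11 fell in the order S2 poly(A), S3 poly(A) and S3 RiboMinus (7, 4 and 4 adjusted over the list alone). Camera gave these an adjusted p of 1.3e-10, 0.381 and 0.308, and of 0.391, 0.778 and 0.772 with the correlation estimated. snoRNA:185 rose by 4.89 ± 0.40, 2.66 ± 0.62 and 0.75 ± 0.28, and 3 of 7, 1 of 8 and 4 of 9 snoRNAs rose (3, 1 and 5 adjusted over the list alone). The adjusted p from camera was 0.00193, 0.638 and 0.144, and 0.471, 0.978 and 0.699 with the correlation estimated. Of long noncoding genes, lncRNA:CR31044 rose by 2.10 ± 0.23, 2.12 ± 0.44 and 1.91 ± 0.39 and lncRNA:CR42862 by 1.73 ± 0.19, 1.20 ± 0.23 and 1.45 ± 0.28. Genes with CR symbols are a mixed list that also holds other RNAs, 18SrRNA:CR41548 and 7SLRNA:CR42652 among them. Of genes with CR symbols 18 of 42 rose and 1 fell, 15 of 48 rose and 3 fell, and 11 of 52 rose (19 and 1, 15 and 3, 11 and 1 adjusted over the list alone). By camera the list had an adjusted p of 0.00329, 0.051 and 0.0531, and of 0.391, 0.481 and 0.699 with the correlation estimated. Of 75 tRNA genes tested in S3 RiboMinus RNA, 35 fell and 1 rose (43 and 1 adjusted over the list alone; median -1.44). Camera gave them an adjusted p of 2.1e-08, and of 0.699 with the correlation estimated. In S3 poly(A) RNA, tRNA:Asp-GTC-2-1 was the 1 of 4 that fell (1 adjusted over the list alone; camera adjusted p 0.466). DESeq2 called 0 tRNA genes lower in S3 RiboMinus RNA and 1 higher, and edgeR without the depth block 0. Without the block 2, 2 and 0 snRNAs, 0, 1 and 0 snoRNAs and 0, 9 and 0 CR genes were higher, and DESeq2 called 6, 4 and 0, then 2, 1 and 3, and then 14, 16 and 4 higher. In every fit that left out 1 library, 4, 1 and 0 snRNAs, 2, 1 and 0 snoRNAs and 6, 9 and 0 CR genes were higher, and 0 tRNA genes were lower. Changes of tRNAs, snRNAs, snoRNAs and rRNA are uncertain, since copies share reads, small RNAs are partly lost in library preparation, and RiboMinus and poly(A) selection treat them differently. EdgeR no longer calls snRNA:U6atac in S3 poly(A) RNA labelled Rrp6 knockdown without GFP replicate 1, GFP replicate 2 or the deeper Rrp6 library. In S3 poly(A) RNA the call of snRNA:U12 ends without GFP replicate 1, GFP replicate 3, the deeper Rrp6 library or the shallower Rrp6 library. It also drops lncRNA:CR31044 in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library. In S3 RiboMinus RNA the call of lncRNA:CR42862 ends without the deeper GFP library or the deeper Rrp6 library. That of snoRNA:185 there ends when any 1 library is left out.

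Ranks of the lists in the authors' deposited tables of Rrp6, set as a description before the data were examined, place each median log2 change among 10000 random lists matched on expression. In the order S2 poly(A), S3 poly(A) and S3 RiboMinus, cell cycle genes of the authors' deposited tables lay at percentiles 0, 0 and 0, ribosomal protein genes at 18.2, 0 and 0, and insulator genes at 0.06, 12.8 and 28.0. JAK-STAT genes of the authors' deposited tables were at 90.5, 100 and 97.7, apoptosis and DNA damage genes at 98.0, 99.9 and 88.9, heat shock genes at 79.8, 90.7 and 2.47, and neuronal genes at 98.7, 49.7 and 99.2. snRNAs of the authors' deposited tables were at 100, 57.7 and 34.8, snoRNAs at 99.1, 90.2 and 93.5, CR genes at 23.8, 56.0 and 99.1, and exosome genes at 2.82, 1.68 and 9.23. tRNAs of the authors' deposited tables were at 2.19, 0 and 0 although their medians were 1.21, 1.87 and -1.30, and among random lists not matched on expression they were at 100, 99.99 and 0. Of 30 cell cycle genes, 7 passed DESeq as lower in the authors' deposited table of S3 poly(A) RNA (19 adjusted over the list alone), CycB and Mcm7 among them, and of 17 snRNAs 3 passed as higher in that of S2 poly(A) RNA (7 adjusted over the list alone).

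**Figure D3:**
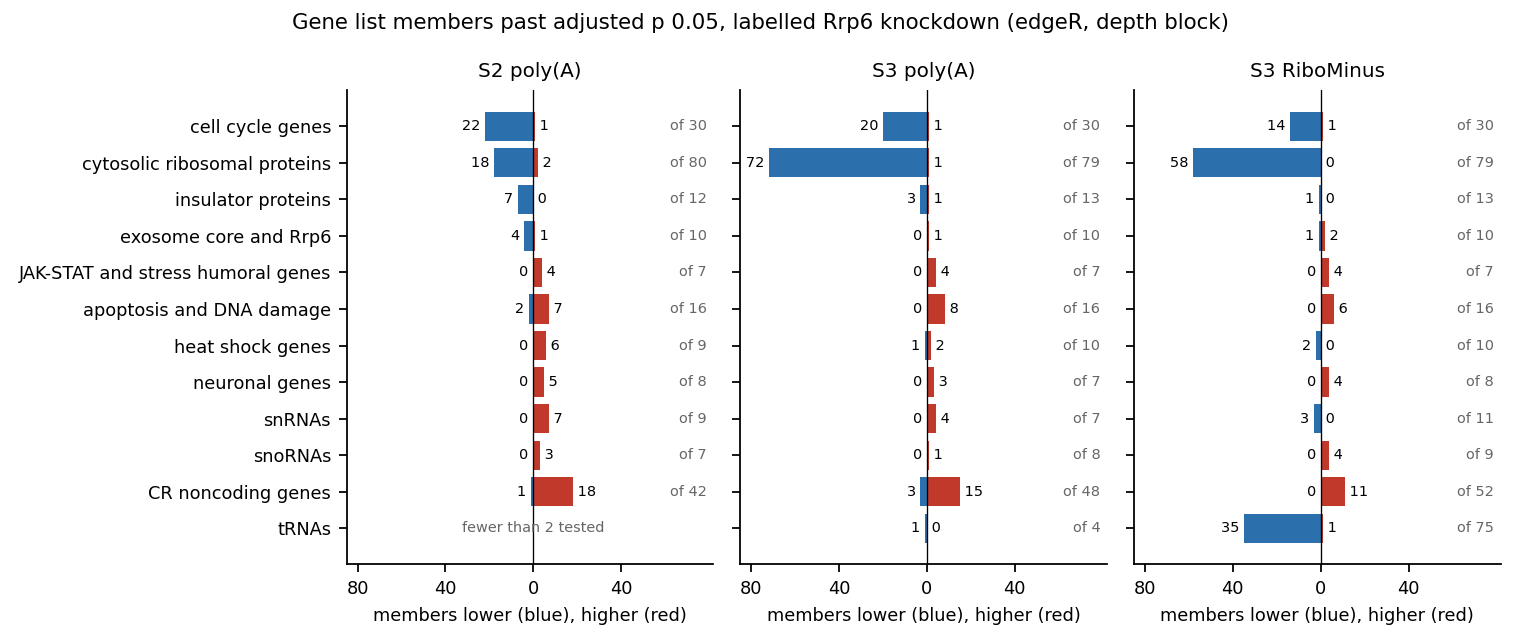
Members of 12 gene lists past edgeR's adjusted p of 0.05 in the libraries labelled Rrp6 knockdown. Ribosomal protein genes fell in 18 of 80 cases in S2 poly(A), 72 of 79 in S3 poly(A) and 58 of 79 in S3 RiboMinus RNA.

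S3 RiboMinus RNA of the libraries labelled Rrp6 knockdown gave changes close to those of poly(A) RNA. CG15347 rose by 6.23 ± 0.63, CG8620 by 6.03 ± 0.37, IRSp53 by 4.15 ± 0.47 and sr, an EGR-type transcription factor gene, by 4.05 ± 0.39, while CG17896 (-2.43 ± 0.33) and Ts (-2.06 ± 0.36) fell. FASN2, a fatty acid synthase gene, fell here (-1.19 ± 0.29, edgeR adjusted p 5.4e-04) and rose in S2 poly(A) RNA (2.93 ± 0.28, edgeR adjusted p 8.6e-08). EdgeR with the depth block called 1027 genes higher and 609 lower of 8286, 15 and 0 without the block (833 genes at an unadjusted p under 0.05), 725 and 391 with the block on this knockdown's libraries and their GFP controls alone, and DESeq2 540 and 192. The total of 1636 became 165 without the deeper GFP library and 348 without the deeper Rrp6 library. In the authors' deposited table, DESeq passed 327 genes higher and 16 lower of 12260, and 289 of the 343 have a mean normalised count under 20. Of 7698 genes tested in both S3 fractions, 773 rose in both against 179 expected of independent lists, 514 fell in both against 96.7, and 1 went opposite ways (r of 0.86 across genes, which are not independent replicates). Of 273 genes called in the authors' deposited table of S3 poly(A) RNA and present in that of RiboMinus RNA, 268 had the same sign (98.2%, 95% interval 95.8 to 99.4), and 26 of 29 did in S2 (89.7%, 72.6 to 97.8). The interaction test of edgeR between fractions passed 0 genes for Rrp6, with 366 at an unadjusted p under 0.05. No other tool was run on it. Replicate numbers of Rrp6 and GFP recur in both fractions by the labels, so the fractions may not be independent. The interaction test did not pair them. The S2 RiboMinus comparison has 1 library per group, and in the authors' deposited table DESeq passed 0 of 7561 genes, with 133 at an unadjusted p under 0.05; edgeR and DESeq2 were not run on it. EdgeR loses the call of CG15347 in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library. The calls of FASN2 and Ts there end without the deeper GFP library or the deeper Rrp6 library. For S3 RiboMinus RNA labelled Rrp6 knockdown, too few reads were left to test CG15347 without the deeper Rrp6 library.

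Libraries labelled Csl4 knockdown showed part of the same set. In S2 poly(A) RNA, CG15347 rose by 3.22 ± 0.31, Cyp6d2 by 2.92 ± 0.33, IRSp53 by 2.78 ± 0.30, Arc1 by 1.47 ± 0.20 and p53 by 1.49 ± 0.23, and kuk fell (-1.22 ± 0.25; edgeR adjusted p 1.6e-06 (CG15347) to 0.00778 (kuk)). snRNA:U12 rose by 3.42 ± 0.29 there, and 4 of 9 snRNAs rose (6 adjusted over the list alone). Camera gave these an adjusted p of 6.3e-21, and of 0.496 with the correlation estimated. In S3 poly(A) RNA Ir40a rose by 3.16 ± 0.33 and the single lower gene was AcCoAS, the acetyl-CoA synthase gene (-1.62 ± 0.24), which was named after its value was seen. In S3 RiboMinus RNA, Cyp6d2 rose by 4.16 ± 0.43, sr by 3.23 ± 0.39 and lncRNA:CR31044 by 2.00 ± 0.38, CycB fell (-1.17 ± 0.35, edgeR adjusted p 0.0416). Of 79 ribosomal protein genes there, 6 fell (10 adjusted over the list alone). The adjusted p from camera was 2.0e-22, and 0.579 with the correlation estimated. Without the block edgeR called 0 members of these lists in either set, DESeq2 4 snRNAs and 3 ribosomal protein genes, and in every fit that left out 1 library 3 snRNAs and 0 ribosomal protein genes kept the call. EdgeR with the depth block called 144 genes higher and 11 lower in S2 poly(A), 18 and 1 in S3 poly(A), and 140 and 39 in S3 RiboMinus RNA. Without the block it called 0, 0 and 1 (151, 370 and 151 genes at an unadjusted p under 0.05), and DESeq2 called 96 and 5, 106 and 44, and 49 and 5. With the block on the libraries of this knockdown and its GFP controls alone, edgeR called 133 and 13, 116 and 46, and 94 and 19, and on all libraries without the filter on low counts 173 and 49, 157 and 52, and 93 and 27. The totals of 155, 19 and 179 fell to 64 without the deeper and 98 without the shallower Csl4 library in S2. In S3 poly(A) RNA they fell to 1 without the deeper and 0 without the shallower Csl4 library, 0 without GFP replicate 1 or 2 and 3 without GFP replicate 3, and in S3 RiboMinus RNA to 2 without the deeper GFP, 21 without the deeper Csl4 and 72 without the shallower Csl4 library. DESeq passed, in the authors' deposited tables, tRNA:Glu-CTC-5-1Psi higher and CG31231 lower in S2 poly(A) RNA, the gene FBgn0085818 higher in S3 poly(A) RNA and Csl4 in S2 RiboMinus RNA, as the only genes. For S3 RiboMinus RNA, the authors' deposited table has 52 genes higher by DESeq and tRNA:Arg-TCG-1-1 lower, and 50 of these 53 have a mean normalised count under 20. EdgeR no longer calls kuk in S2 poly(A) RNA labelled Csl4 knockdown without GFP replicate 1 or the deeper Csl4 library. It also drops Ir40a in S3 poly(A) RNA labelled Csl4 knockdown without GFP replicate 1, GFP replicate 2, the deeper Csl4 library or the shallower Csl4 library. The call of AcCoAS ends when any 1 library is left out. It further drops lncRNA:CR31044 in S3 RiboMinus RNA labelled Csl4 knockdown without the deeper Csl4 library or the deeper GFP library. The call of CycB there ends when any 1 library is left out, that of Cyp6d2 and sr without the deeper GFP library.

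Calls in libraries labelled Rrp40 knockdown depended on the fit. In S2 poly(A) RNA 1 library has this label, so SE and p assume that it varies like the other groups and hold no spread of its own. There lncRNA:CR31044 was higher by 2.63 ± 0.29, snRNA:U12 by 3.05 ± 0.36, FASN2 by 2.43 ± 0.37 and the vesicle priming gene unc-13 by 1.53 ± 0.27 (edgeR adjusted p 1.8e-05 (lncRNA:CR31044) to 0.013 (unc-13)). In S3 RiboMinus RNA lncRNA:CR31044 rose by 2.67 ± 0.39, Cyp6d2 by 2.36 ± 0.42, sr by 2.14 ± 0.40 and Ir40a by 1.83 ± 0.41. The epidermal transcription factor gene grh fell (-3.34 ± 0.65, edgeR adjusted p 3.8e-04), as did tRNA:Lys-TTT-1-1 (-1.36 ± 0.35, edgeR adjusted p 0.0366). Ir40a, grh and this tRNA were named after their values were seen. EdgeR with the depth block called 8 genes higher and 0 lower in S2 poly(A), 0 in S3 poly(A) (437 genes at an unadjusted p under 0.05) and 16 higher and 2 lower in S3 RiboMinus RNA. Without the block it called 0 in each set (35, 168 and 25 genes at an unadjusted p under 0.05), and DESeq2 called 7, 50 and 4 genes. On the libraries of this knockdown and its GFP controls alone, edgeR with the block called 221 higher and 84 lower in S3 poly(A) and 16 and 7 in S3 RiboMinus RNA. With all libraries and without the filter on low counts it called 90 and 3 in S3 poly(A) RNA. The total of 8 in S2 became 14 without GFP replicate 1 and 15 without GFP replicate 3. With S3 poly(A) RNA, 11 genes passed without the shallower Rrp40 library and 2 without the deeper one, and in S3 RiboMinus RNA the 18 fell to 1 without the deeper GFP library and 2 without the deeper Rrp40 library. As for the authors' deposited tables, DESeq passed 6 genes higher and CG31231 lower in S2 poly(A) RNA, and Eno and 7SLRNA:CR42652 higher in S2 RiboMinus RNA. DESeq passed, in the authors' deposited table of S3 poly(A) RNA, 205 genes higher and 7 lower, of which 209 have a mean normalised count under 20. DESeq passed 22 genes higher and 2 lower (CG10814 and tRNA:Tyr-GTA-1-5) in the authors' deposited table of S3 RiboMinus RNA, and 24 of these 24 have such low counts. Of 195 genes called in the authors' deposited table of S3 poly(A) RNA, 110 had the same sign in that of RiboMinus RNA (56.4%, 49.1 to 63.5); in S2 5 of 6 did, and 1 of 1 for Csl4 in S3. EdgeR loses the call of unc-13 in S2 poly(A) RNA labelled Rrp40 knockdown without GFP replicate 3. It also drops Cyp6d2, Ir40a, lncRNA:CR31044 and sr in S3 RiboMinus RNA labelled Rrp40 knockdown without the deeper GFP library or the deeper Rrp40 library. The call of tRNA:Lys-TTT-1-1 ends without the deeper GFP library, the deeper Rrp40 library or the shallower Rrp40 library. For S3 RiboMinus RNA labelled Rrp40 knockdown, too few reads were left to test grh without the deeper GFP library or the deeper Rrp40 library.

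**Figure D4:**
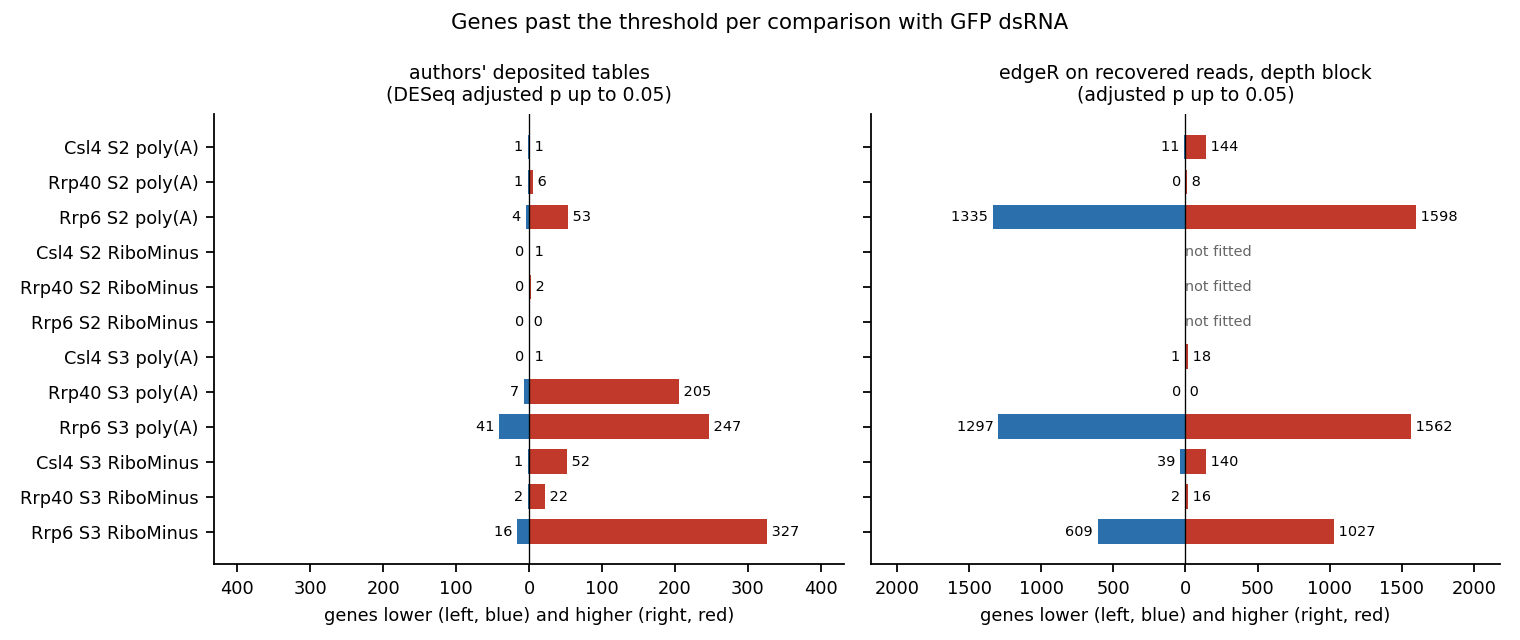
Genes past the threshold in each of the 12 comparisons, from the authors' deposited tables and from edgeR on recovered reads with a depth block. Rrp6 S3 poly(A) RNA gave 247 higher and 41 lower genes in the authors' deposited table, and 1562 and 1297 with edgeR.

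The knockdowns shared changed genes. In S2 poly(A) RNA, 143 of the 144 genes higher in libraries labelled Csl4 knockdown were also higher in those labelled Rrp6 knockdown (29.1 expected of independent lists). Cyp6d2, Arc1 and snRNA:U12 are among them, and 11 of 11 lower genes were also lower, kuk among them. Shared genes were 18 of 18 in S3 poly(A) RNA (3.55 expected), among them Ir40a, and 135 of 140 higher (17.4 expected) and 34 of 39 lower (2.87 expected) in S3 RiboMinus RNA, among them Cyp6d2 and CycB. Of the 8 genes higher in the 1 Rrp40 library of S2, whose own spread is unknown, 6 were also higher with Rrp6 (1.62 expected) and 6 with Csl4 (0.146 expected). In S3 RiboMinus RNA 13 of 16 were shared with Rrp6 (1.98 expected) and 14 with Csl4 (0.27 expected). The knockdowns of a set share their GFP libraries, which makes changes correlate. Between Csl4 and Rrp6, r across genes was 0.81, 0.66 and 0.84 in S2 poly(A), S3 poly(A) and S3 RiboMinus RNA, against 0.48, 0.39 and 0.50 in 20 simulations of unchanged knockdown groups. Rrp40 and Rrp6 gave 0.39, 0.38 and 0.62 against 0.32, 0.38 and 0.49. No gene changes in the simulations, while many change with Rrp6 in the data, so r alone is not a like comparison. The covariance of Rrp40 and Rrp6 was 0.170, 0.166 and 0.229, above the simulated means of 0.044, 0.051 and 0.090. The GFP libraries were too few to be divided between the comparisons. EdgeR's direct test of Rrp6 against Csl4 passed 628 genes higher and 433 lower in S2 poly(A), 579 and 576 in S3 poly(A), and 169 and 35 in S3 RiboMinus RNA; Rrp6 against Rrp40 passed 522 and 365, 1087 and 982, and 629 and 233. Csl4 against Rrp40 passed 1 and 1, 0 and 0, and 4 and 3. The largest shared set in the authors' deposited tables was 28 genes higher with Csl4 and Rrp6 in S3 RiboMinus RNA, sr and Cyp6d2 among them (1.44 expected, Fisher adjusted p 3.1e-29 over 16 tests), and Rrp40 and Rrp6 shared 11 in S3 poly(A) RNA, among them Cyp6d2 and hid (4.31 expected, Fisher adjusted p 0.00746). Most of these genes have low counts: with a mean of at least 10 in both of the authors' deposited tables the 28 became 2 (Fisher adjusted p 6.1e-04) and with at least 100 they became 0. The 11 became 1 with either (Fisher adjusted p 0.0607 and 0.0581) and 4 at an adjusted p of 0.01 (Fisher adjusted p 0.153), so that overlap depends on the threshold and on low counts.

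Many genes changed the same way in S2 and S3 poly(A) RNA labelled Rrp6 knockdown. CycB, Mcm7, p53 and Arc1 moved the same way in both lines, and of 7283 genes tested in both, 828 rose in both against 246 expected of independent lists. A further 721 fell in both against 227, and 33 moved in opposite ways (r of 0.74 across genes). In both lines 28 genes were higher in the authors' deposited tables (1.13 expected, Fisher adjusted p 9.8e-33 over 7 tests), among them Tdh, ppk13 and Ect3, and 1, kuk, was lower in both (Fisher adjusted p 0.0334). The interaction test of edgeR passed 162 genes with a more positive and 75 with a more negative response in S3 than in S2, of 8984, with 1360 at an unadjusted p under 0.05. Among them hid differed by 3.30 and upd3 by 2.71 (adjusted p 0.0075 and 0.0292 in edgeR's interaction test), and snRNA:U12 by -4.16 and snRNA:U11 by -3.17 (adjusted p 0.0018 and 0.00387 in the same edgeR test). Of 81 ribosomal protein genes, RpL36, RpL3, RpL15 and RpL8 passed with a more negative response in S3, and the list's median difference was -1.12. Cell cycle genes gave 0 of 30, with a median difference of -0.15, and no other tool was run on the interaction. The same test passed 0 genes for Csl4 (339 at an unadjusted p under 0.05) and 0 for Rrp40 (205).

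Rrp6 and Rrp40 peaks coincided. Of 3282 Rrp6 peaks in S2, 81.8% overlapped 1 of the 3750 Rrp40 peaks, against a mean of 13.3% for 1000 circular shifts within chromosome arms, and of 2746 Rrp6 peaks in S3 81.1% overlapped 1 of 2831 Rrp40 peaks, against 10.6%. The lines shared most peaks: 66.4% of Rrp6, 69.8% of Rrp40 and 71.8% of Su(Hw) peaks of S2 overlapped a peak of the same antibody in S3, against 9.89, 10.5 and 9.79%. Su(Hw), a zinc finger protein that binds insulators, lay at exosome peaks more often in S2 than in S3, with an odds ratio of 2.85 for Rrp6 and 2.85 for Rrp40 (Fisher adjusted p 2.1e-39 and 3.1e-38). Peaks are not independent replicates and the lines shared most of them, so these Fisher p-values measure no spread between samples of a line. In S2 19.3% of Rrp6 and 17.3% of Rrp40 peaks overlapped 1 of 2084 Su(Hw) peaks, against 7.18 and 8.16% for the shifts. In S3 7.76% of Rrp6 and 6.82% of Rrp40 peaks overlapped 1 of 2598 Su(Hw) peaks, below the 10.3 and 9.66% of the shifts (one-sided p for fewer overlaps 0.001, a side added after the values were seen). Either exosome subunit was found at 755 of 2084 Su(Hw) peaks in S2 (36.2%) and at 252 of 2598 in S3 (9.7%). Each excess over the shifts within a line or an antibody has a one-sided p of 0.001, the smallest that 1000 shifts can give, and an adjusted p of 0.00136 over the 15 pairs of circular-shift tests. Across lines Su(Hw) peaks of S2 overlapped Rrp6 peaks of S3 in 24.2% against 10.5% and Rrp40 peaks of S3 in 22.4% against 9.98% (adjusted p of the shifts 0.00136 each). Rrp6 peaks of S2 overlapped Su(Hw) peaks of S3 in 9.29% against 9.05% (one-sided p 0.33, adjusted p of the shifts 0.415) and Rrp40 peaks of S2 in 8.37% against 10.2%. By 1 bp and these shifts, the excess thus went with the Su(Hw) list of S2 and not with the exosome peaks of S2. Some other rules put Rrp6 peaks of S2 above the shifts at Su(Hw) peaks of S3 too. With an overlap of at least 0.5 of the shorter peak they were at 7.71% against 5.39%. With midpoints within 250 bp it was 4.30% against 1.07%. With shifts of 5 to 50 kb it was 9.29% against 7.97% (adjusted p of the shifts 0.0112). Rrp40 peaks of S2 passed with midpoints alone (3.12% against 1.08%). The S3 deficit depends on the rule for overlap: with midpoints within 250 bp, 2.66% of Rrp6 and 2.33% of Rrp40 peaks were at Su(Hw) peaks of S3, above the shifts (one-sided p 0.001). With an overlap of at least 0.5 of the shorter peak neither was below them (one-sided p for fewer overlaps 0.454 and 0.351), and with shifts of 5 to 50 kb it was 0.0549 for Rrp6 and 0.00999 for Rrp40. Each list was called once per antibody and line, from pooled technical replicates for Rrp6 and Rrp40 and from 1 sample for Su(Hw), so no spread between replicates exists. Median widths were 2024 and 2322.5 bp for Rrp6 and Rrp40 in S2, 2225 and 2056 bp in S3, and 2105.5 and 2132 bp for Su(Hw) in S2 and S3. Overlap with promoters was not analysed here, since no gene annotation for the peaks' genome build was at hand.

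**Figure D5:**
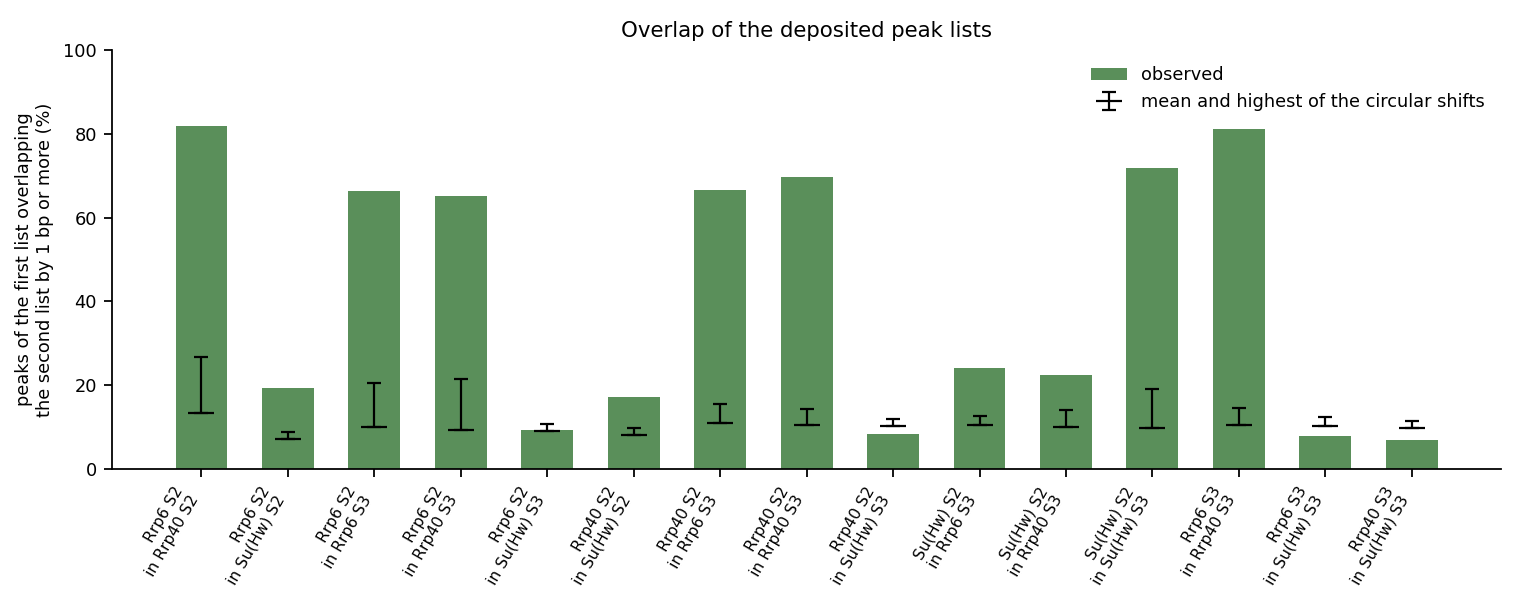
Share of peaks of the first list that overlap the second by 1 bp or more (bars), with the mean and the highest of 1000 circular shifts. Rrp6 peaks overlap Su(Hw) peaks in 19.3% of cases in S2, against 7.18% for the shifts, and in 7.76% in S3, against 10.3%.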

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

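The tests between lines and fractions, on the targeted genes, on the Su(Hw) peaks, on the Rrp40 calls and on reads in the shallower libraries were chosen after the results were seen, and that on the sign of the Rrp6 RiboMinus calls before. The rule for the targeted genes, over 10-fold with at least 10 reads, replaced a first rule on the authors' adjusted p, which 5 of 12 tables met and which left the question open.

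The response to Rrp6 dsRNA in poly(A) RNA was flagged as differing between lines by edgeR's interaction test: 162 genes were more positive and 75 more negative in S3 than in S2. Among named genes the differences were -5.02 for Alp9, -4.16 for snRNA:U12, -3.17 for snRNA:U11, -2.62 for snRNA:U2:34ABa, 2.71 for upd3, 3.30 for hid and 3.95 for lncRNA:CR42746 (adjusted p in edgeR's interaction test 0.00113, 0.0018, 0.00387, 0.0227, 0.0292, 0.0075 and 0.0194). For Rrp40 in S3, 3 genes were more negative in RiboMinus than in poly(A) RNA: snRNA:U5:63BC, tRNA:Lys-TTT-1-1 and tRNA:Asn-GTT-1-8, small RNAs that both selections treat differently. The overlap of Rrp6 and Rrp40 peaks with Su(Hw) peaks differed between lines, with odds ratios of 2.85 for S2 over S3. The cause of these differences was not tested, except as below. No group had 4 libraries, as 2 of the 4 GFP samples of S3 poly(A) RNA are technical runs of replicate 2 per the labels, so no library could be flagged as an outlier within its group.

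Many calls in the authors' deposited tables sit at mean counts under 20: 209 for Rrp40 in S3 poly(A) RNA and 289 for Rrp6 in S3 RiboMinus RNA. At means below 2.05 and 1.59 no gene can have a read in a shallower library, which leaves 129 and 136 of these genes to compare with uncalled genes of like mean count. Of them 84.5 and 87.5% have no read in either shallower library, against 14.6 and 20.5% (Mantel-Haenszel p 1.3e-56 and 4.0e-60 over bins of the mean). These calls thus rest mostly on the deeper library of each group, as a gap in depth between the averaged libraries predicts. A change with the knockdown predicts the same sign in the other fraction, and 94.4% of 213 Rrp6 genes had it (90.4 to 97.1, uncalled genes 68.7%). Of 192 Rrp40 genes 55.7% had it (48.4 to 62.9, uncalled genes 49.9%). With a median of 6 reads in the group that had fewer of them in RiboMinus RNA, this leaves a change of the Rrp40 genes open. Replicate numbers of the labels recur in both fractions, so the same sign could also come from a deviation of a shared replicate. EdgeR with the depth block called 63 of 151 tested Rrp6 genes and 0 of 40 tested Rrp40 genes, the latter in a fit that called 0 of all 7923 genes, so it decides nothing about them.

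Targeted genes have more reads in the libraries labelled as their knockdown, over 10-fold in 11 of 12 tables. Reads from the transfected dsRNA and more of the gene's own mRNA both predict this and cannot be told apart here, since the largest difference between fractions in S3, 3.66 for Rrp6, had an adjusted p of 0.85 in edgeR's interaction test. In S2 the authors' deposited tables give 3.73 in poly(A) and 11.17 in RiboMinus RNA for Rrp6 and 4.80 and 10.30 for Rrp40, and Csl4 has 0 GFP reads against 1668 in RiboMinus RNA. A larger excess in RiboMinus RNA is what dsRNA without a poly(A) tail predicts, but with 1 RiboMinus library per group in S2 it has no spread to be tested against. Eno, which overlaps Rrp40, is over 2-fold higher in 4 of 4 Rrp40 tables and 0 of 8 others, which both predict if reads were counted without regard to strand. For S3 poly(A) RNA that rests on 1 library, with Eno at 9.08-fold in the shallower and 0.841-fold in the deeper Rrp40 library (edgeR adjusted p 0.766). A swap between knockdowns is argued against by 0 of 24 pairings of a targeted gene with another knockdown over 10-fold. A GFP library labelled as a knockdown would not show in these pairings. Reads along the genes, which would separate the open explanations, were not analysed here.

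Counting overlaps of 1 bp, Su(Hw) and exosome peaks overlap above the shifts in S2 and not in S3, while with midpoints within 250 bp they do in S3 as well (2.66% of Rrp6 and 2.33% of Rrp40 peaks, one-sided p 0.001). Of the 587 Su(Hw) peaks of S2 with no S3 counterpart, 69.7% overlap Rrp6 peaks of S2, against 15.3% of the 1497 shared ones. Such a split follows in part from the low overlap in S3. Both peaks found with any antibody in the S2 list and Su(Hw) bound in S2 alone at exosome sites predict it. A like split was asked of S3, and it was not seen. Peaks particular to the S2 sample predict no split in S3, so its absence does not set the former apart. Of Su(Hw) peaks of S3 with no S2 counterpart, 7.02% overlap Rrp6 peaks of S3, against 9.13% of the shared ones. The shared peaks overlap Rrp6 in S2 in 15.3% against 11.7% for the shifts (one-sided p 0.001, the smallest possible), but Rrp40 in 15.2% against 14.8% (one-sided p 0.35). Of the 587, 61.7% also overlap Rrp6 peaks of S3, against 8.78% for the shifts (one-sided p 0.001). Rrp40 peaks of S2 and S3 overlap 73.1 and 58.6% of the 587, against 12.2 and 8.27% for the shifts. The median width of the 587 is 1499 bp, against 2287 bp for the shared peaks of S2. With 1 Su(Hw) sample per line these explanations cannot be told apart.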

How the results depend on the processing

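Fits on the recovered reads and the side of the shifts for fewer overlaps were added after the files were seen, the other settings before. No paired analysis was possible because the knockdown libraries cannot be tied to a replicate number, except that by depth: the depth block on a knockdown's own libraries pairs its deeper and its shallower library with those of GFP. Not run were the promoter results and the settings on peak scores, for want of a dm3 annotation and of scores, and the technical runs apart, which the files do not hold. Where leaving out a library leaves 1 in a group, that library is assumed to vary like the other groups. In S3 RiboMinus RNA, fits without a deeper library tested 3690 to 3755 genes, against 8286 with all libraries.

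Numbers of called genes in the authors' deposited tables moved with an adjusted p of 0.01 to 1 in S2 poly(A), 30 in S3 RiboMinus for Csl4, 23 in S2 poly(A), 153 in S3 poly(A), 218 in S3 RiboMinus for Rrp6. At 0.1 they moved to 3 in S3 poly(A) for Csl4, 96 in S2 poly(A), 1 in S2 RiboMinus for Rrp6. An absolute log2 fold change of at least 1 left 12 in S3 RiboMinus for Rrp40. With p adjusted again over the genes of a mean count of at least 10 they were 1 in S2 poly(A), 2 in S2 RiboMinus, 3 in S3 poly(A), 0 in S3 RiboMinus for Csl4, 0 in S3 poly(A), 0 in S3 RiboMinus for Rrp40, 1 in S2 RiboMinus, 39 in S3 RiboMinus for Rrp6. With p adjusted again over those of at least 100 they were 1 in S2 poly(A), 3 in S3 poly(A), 1 in S3 RiboMinus for Csl4, 4 in S2 poly(A), 1 in S2 RiboMinus, 0 in S3 poly(A), 0 in S3 RiboMinus for Rrp40, 3 in S2 RiboMinus, 165 in S3 poly(A), 9 in S3 RiboMinus for Rrp6.

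EdgeR on the recovered reads with the depth block called 155 in S2 poly(A), 19 in S3 poly(A), 179 in S3 RiboMinus for Csl4, 0 in S3 poly(A) for Rrp40, 2933 in S2 poly(A), 2859 in S3 poly(A), 1636 in S3 RiboMinus for Rrp6. Without the block it called 0 in S2 poly(A), 0 in S3 poly(A), 1 in S3 RiboMinus for Csl4, 0 in S2 poly(A), 0 in S3 poly(A), 0 in S3 RiboMinus for Rrp40, 9 in S2 poly(A), 1076 in S3 poly(A), 15 in S3 RiboMinus for Rrp6. Without the filter on low counts the calls were 222 in S2 poly(A), 209 in S3 poly(A), 120 in S3 RiboMinus for Csl4, 17 in S2 poly(A), 93 in S3 poly(A), 14 in S3 RiboMinus for Rrp40, 3266 in S2 poly(A), 4504 in S3 poly(A), 1521 in S3 RiboMinus for Rrp6. RLE scaling gave 224 in S2 poly(A), 19 in S3 poly(A), 180 in S3 RiboMinus for Csl4, 11 in S2 poly(A), 9 in S3 poly(A) for Rrp40, 2985 in S2 poly(A), 2830 in S3 poly(A), 1634 in S3 RiboMinus for Rrp6. DESeq2 with the block gave 101 in S2 poly(A), 150 in S3 poly(A) for Csl4, 50 in S3 poly(A), 4 in S3 RiboMinus for Rrp40, 1866 in S2 poly(A), 3079 in S3 poly(A), 732 in S3 RiboMinus for Rrp6. On the libraries of the knockdown and its controls alone, edgeR without the block called 0 in S2 poly(A), 0 in S3 poly(A), 1 in S3 RiboMinus for Csl4, 0 in S3 poly(A), 0 in S3 RiboMinus for Rrp40, 0 in S2 poly(A), 7 in S3 poly(A), 16 in S3 RiboMinus for Rrp6. With the block on those libraries it called 146 in S2 poly(A), 162 in S3 poly(A), 113 in S3 RiboMinus for Csl4, 3022 in S2 poly(A), 785 in S3 poly(A), 1116 in S3 RiboMinus for Rrp6, and for Rrp40 305 in S3 poly(A) (221 higher and 84 lower, against 205 and 7 in the authors' deposited table) and 23 in S3 RiboMinus.

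Leaving out each library in turn, edgeR with the block called 64 to 164 in S2 poly(A), 0 to 3 in S3 poly(A), 2 to 136 in S3 RiboMinus for Csl4, 14 to 15 in S2 poly(A), 0 to 11 in S3 poly(A), 1 to 22 in S3 RiboMinus for Rrp40, 1169 to 2721 in S2 poly(A), 1149 to 4190 in S3 poly(A), 165 to 1573 in S3 RiboMinus for Rrp6.

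Each gene list of the authors' deposited tables of Rrp6 was ranked again, as a percentile among random lists. With a mean count of at least 10, newly outside in S2 poly(A) are JAK-STAT 98.9, heat shock genes 99.3, no longer outside in S2 poly(A) are apoptosis and DNA damage 93, on the other side in S2 poly(A) are CR noncoding genes 99.2, newly outside in S3 poly(A) are snRNAs 99. With random lists not matched on expression, newly outside in S2 poly(A) are ribosomal proteins 0.08, exosome core and Rrp6 1.13, no longer outside in S2 poly(A) are snoRNAs 95.1, apoptosis and DNA damage 72.5, on the other side in S2 poly(A) are tRNAs 100, CR noncoding genes 100, no longer outside in S3 poly(A) are apoptosis and DNA damage 87.4, on the other side in S3 poly(A) are tRNAs 99.99, newly outside in S3 poly(A) are CR noncoding genes 100, no longer outside in S3 RiboMinus are JAK-STAT 95.5, heat shock genes 3.37, neuronal genes 97. With 1 added to both means, no longer outside in S2 poly(A) are snoRNAs 96.6, tRNAs 31.8, neuronal genes 95.1, no longer outside in S3 poly(A) are tRNAs 2.54, newly outside in S3 RiboMinus are snoRNAs 99.1, no longer outside in S3 RiboMinus are JAK-STAT 95, CR noncoding genes 96.5.

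Shared calls of the authors' deposited tables moved in 8 cases. At an adjusted p of 0.01, Rrp40 and Rrp6 shared 4 higher genes in S3 poly(A) RNA, no longer past the Fisher test (adjusted p 0.153), and Rrp6 shared 0 lower genes between lines. At 0.1, Csl4 and Rrp40 shared 2 higher genes in S3 poly(A) and 1 lower gene in S3 RiboMinus RNA, newly past it (Fisher adjusted p 0.00182 and 0.00111). With a mean of at least 100 in both tables, Rrp40 and Rrp6 shared 0 higher genes in S2 and 1 in S3 poly(A) RNA (Fisher adjusted p 0.0581), and with at least 10 1 gene in S3 (0.0607). With at least 10, the 1 gene higher with Rrp40 in both lines, FASN2, passed (Fisher adjusted p 0.00251). With at least 100 in both, the share of genes with the same sign in both fractions was 100% for Rrp40 in S2 (1 of 1), 100% for Rrp40 in S3 (2 of 2) and 100% for Rrp6 in S2 (4 of 4).

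Overlap with Su(Hw) peaks of S3 depended on the rule. Counting overlaps of at least 0.5 of the shorter peak, 7.71% of Rrp6 peaks of S2 lay above the shifts and 6.75% of Rrp40 peaks of S2 were on the other side of them (p 0.0726). With midpoints within 250 bp, Rrp6 of S2 at 4.30% passed, and Rrp40 of S2 at 3.12%, Rrp6 of S3 at 2.66% and Rrp40 of S3 at 2.33% turned from below the shifts to above. With at least 0.5 of the shorter peak, Rrp6 of S3 at 6.05% and Rrp40 of S3 at 5.40% were no longer below the shifts (p for fewer overlaps 0.454 and 0.351). With shifts of 5 to 50 kb Rrp6 of S2 at 9.29% passed (p 0.0112), and p for fewer overlaps was 0.0549 for Rrp6 and 0.00999 for Rrp40 of S3.

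The remaining results are given as numbers. For 237 pairs of a named gene and a refit with edgeR or DESeq2, 184 kept the call and 53 lost it, 36 of the latter without the depth block. Of the overlaps of knockdowns 38 stayed on the same side of the threshold, though the 28 genes of Csl4 and Rrp6 became 2 with a mean of at least 10, of those of lines 18, of peak overlaps 53, and of the ranks of gene lists 82. The targeted genes kept their direction in 11 of 11 cases, and peak numbers were the same in 6 of 6. Keeping the main chromosome arms alone left 21 of 21 results the same, and adjusting the authors' p again left 12 of 12. Members of lists past the threshold in edgeR moved in 41 cases and stayed in 29. The cause of these moves was not tested, apart from the depth of the libraries.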

Other observations

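Tests in this part on recovered reads were chosen after the files were seen, and all values are for the libraries labelled Rrp6 knockdown. Epithelial and imaginal disc markers rose in S2 poly(A) RNA, 6 of 8 (6 adjusted over the list alone; median 1.02; camera adjusted p 0.0103, and 0.396 with the correlation estimated), with 3 of 7 in S3 poly(A) and 1 of 6 in S3 RiboMinus RNA (3 and 1 adjusted over the list alone; camera adjusted p 0.0857 and 0.308). Among them the polarity gene crb changed by 0.90 ± 0.28, 3.04 ± 0.41 and 1.55 ± 0.56. Of the ecdysone response genes 6 of 12 rose and 1 fell in S2, 5 and 2 of 10 in S3 poly(A) and 3 and 1 of 12 in S3 RiboMinus RNA (7 and 1, 7 and 2, and 3 and 1 adjusted over the list alone; camera adjusted p 0.0231, 0.396 and 0.22, the first 0.391 with the correlation estimated), with ImpL2, an insulin antagonist gene, at 1.81 ± 0.22, 2.33 ± 0.74 and 1.19 ± 0.29. Oxidative stress and detoxification genes went both ways: 7 of 14 higher and 1 lower, 5 and 4 of 16, and 4 and 3 of 16 (7 and 1, 6 and 4, and 5 and 5 adjusted over the list alone; camera adjusted p 0.0368, 0.577 and 0.863, the first 0.396 with the correlation estimated), with Gclc, for glutathione synthesis, at 1.20 ± 0.22, 2.28 ± 0.28 and 1.41 ± 0.28 and Sod2 at -1.06 ± 0.22, -1.58 ± 0.24 and -1.21 ± 0.37. Of 14 small RNA silencing genes 3 rose in each set (3 adjusted over the list alone; camera adjusted p 0.729, 0.557 and 0.278), Dcr-2 by 1.24 ± 0.25, 1.33 ± 0.24 and 1.55 ± 0.30. Higher and lower members in the same order follow. For epithelial markers edgeR without the depth block called 0, DESeq2 4 and 0, 3 and 0, and 0 and 0, and every fit that left out 1 library 2 and 0, 0 and 0, and 0 and 0. For ecdysone genes edgeR without the depth block called 0 and 0, 2 and 0, and 0 and 0, DESeq2 4 and 0, 7 and 2, and 2 and 1, and every fit that left out 1 library 3 and 0, 0 and 0, and 1 and 1. For oxidative stress genes edgeR without the depth block called 0 and 0, 2 and 1, and 0 and 0, DESeq2 4 and 1, 6 and 4, and 2 and 1, and every fit that left out 1 library 2 and 1, 1 and 2, and 0 and 1. For silencing genes edgeR without the depth block called 0 and 0, 1 and 0, and 0 and 0, DESeq2 2 and 0, 4 and 0, and 2 and 0, and every fit that left out 1 library 2 and 0, 1 and 0, and 0 and 0. EdgeR loses the call of crb in S2 poly(A) RNA labelled Rrp6 knockdown without GFP replicate 1 or the deeper Rrp6 library. It also drops ImpL2 in S3 poly(A) RNA labelled Rrp6 knockdown without GFP replicate 1, GFP replicate 2 or the deeper Rrp6 library. The call of crb there ends without the deeper Rrp6 library. It further drops Gclc in S3 RiboMinus RNA labelled Rrp6 knockdown without the deeper GFP library. The calls of Dcr-2, ImpL2 and Sod2 there end without the deeper GFP library or the deeper Rrp6 library, that of crb without the shallower GFP library. For S3 RiboMinus RNA labelled Rrp6 knockdown, too few reads were left to test crb without the deeper GFP library or the deeper Rrp6 library.

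Counts of members higher and lower by edgeR follow for the other lists, in the order S2 poly(A), S3 poly(A) and S3 RiboMinus RNA, with those adjusted over the list alone in brackets. NMD factors and targets had 4 and 0 of 9 (5 and 1), 4 and 0 of 9 (4 and 0), and 3 and 0 of 9 (3 and 0), with a camera adjusted p of 0.0231, 0.0576 and 0.22, and of 0.391 in S2 with the correlation estimated. Called were 1 and 0, 3 and 0, and 1 and 0 without the block, 4 and 0, 4 and 0, and 2 and 0 by DESeq2 and 3 and 0, 3 and 0, and 1 and 0 in every fit that left out 1 library. Hemocyte markers had 2 and 1 of 11 (1 and 1), 2 and 2 of 9 (2 and 2), and 0 and 0 of 9 (0 and 0), with a camera adjusted p of 0.876, 0.981 and 0.926. Called were 0 without the block, 1 and 1, 2 and 2, and 0 and 0 by DESeq2 and 0 in every fit that left out 1 library. Muscle and fat body markers had 2 and 0 of 3 (2 and 0), 1 and 0 of 6 (1 and 0), and 2 and 0 of 7 (2 and 0), with a camera adjusted p of 0.137, 0.638 and 0.278. Called were 0 and 0, 1 and 0, and 1 and 0 without the block, 2 and 0, 1 and 0, and 1 and 0 by DESeq2 and 1 and 0, 1 and 0, and 0 and 0 in every fit that left out 1 library. Germline and testis genes had 1 and 2 of 4 (1 and 2), 0 and 1 of 5 (0 and 1), and 0 and 0 of 5 (0 and 0), with a camera adjusted p of 0.647, 0.638 and 0.541. Called were 0 and 0, 0 and 1, and 0 and 0 without the block, 1 and 0, 0 and 1, and 0 and 0 by DESeq2 and 1 and 0, 0 and 0, and 0 and 0 in every fit that left out 1 library. Antimicrobial and immune genes had 0 and 2 of 16 (0 and 1), 2 and 0 of 3 (2 and 0), and 0 and 0 of 3 (0 and 0), with a camera adjusted p of 0.242, 0.638 and 0.278. Called were 0 without the block, 0 and 1, 2 and 0, and 0 and 0 by DESeq2 and 0 in every fit that left out 1 library. Dosage compensation genes had 2 and 0 of 7 (2 and 0), 1 and 1 of 7 (1 and 1), and 0 and 1 of 7 (0 and 1), with a camera adjusted p of 0.425, 0.958 and 0.863. Called were 0 without the block, 2 and 0, 1 and 1, and 0 and 1 by DESeq2 and 1 and 0, 1 and 1, and 0 and 1 in every fit that left out 1 library. Genes of polymerase II pausing had 2 and 5 of 14 (3 and 7), 3 and 2 of 14 (3 and 3), and 2 and 0 of 14 (1 and 0), with a camera adjusted p of 0.271, 0.973 and 0.863. Called were 0 and 0, 1 and 1, and 0 and 0 without the block, 1 and 1, 3 and 3, and 1 and 0 by DESeq2 and 1 and 0, 1 and 0, and 1 and 0 in every fit that left out 1 library. Polyadenylation genes had 0 and 2 of 12 (0 and 2), 0 and 1 of 12 (0 and 1), and 0 and 0 of 12 (0 and 0), with a camera adjusted p of 0.0646, 0.296 and 0.256. Called were 0 and 0, 0 and 1, and 0 and 0 without the block, 0 and 2, 0 and 1, and 0 and 0 by DESeq2 and 0 and 1, 0 and 1, and 0 and 0 in every fit that left out 1 library. Ribosome biogenesis genes had 0 and 4 of 11 (0 and 4), 0 and 0 of 11 (0 and 0), and 0 and 1 of 11 (0 and 0), with a camera adjusted p of 0.0794, 0.459 and 0.278. Called were 0 without the block, 0 and 2, 0 and 0, and 0 and 0 by DESeq2 and 0 in every fit that left out 1 library. Genes that host snoRNAs had 0 and 1 of 11 (0 and 1), 2 and 3 of 11 (2 and 3), and 0 and 2 of 10 (0 and 2), with a camera adjusted p of 0.973, 0.789 and 0.32. Called were 0 without the block, 0 and 1, 2 and 3, and 0 and 2 by DESeq2 and 0 and 0, 0 and 3, and 0 and 0 in every fit that left out 1 library. Exosome cofactors had 0 and 1 of 8 (0 and 1), 1 and 0 of 9 (0 and 0), and 0 and 0 of 9 (0 and 0), with a camera adjusted p of 0.423, 0.973 and 0.74. Called were 0 without the block, 0 and 1, 1 and 0, and 0 and 0 by DESeq2 and 0 in every fit that left out 1 library. Other abundant noncoding RNAs had 4 and 0 of 4 (4 and 0), 1 and 1 of 4 (2 and 1), and 0 and 1 of 4 (0 and 1), with a camera adjusted p of 0.012, 0.981 and 0.863, and of 0.391 in S2 with the correlation estimated. Called were 0 and 0, 1 and 0, and 0 and 0 without the block, 4 and 0, 2 and 1, and 0 and 1 by DESeq2 and 2 and 0, 0 and 1, and 0 and 1 in every fit that left out 1 library. No histone, scaRNA or mitochondrial gene could be tested with edgeR.

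In the 1 library labelled Rrp40 knockdown of S2 poly(A) RNA, where p assumes that it varies like the other groups, 2 of 9 snRNAs were called higher, and 6 when adjusted over the list alone (camera adjusted p 7.4e-12, and 0.597 with the correlation estimated). Of those in S3 poly(A) RNA labelled Rrp40 knockdown, 0 of 7 were called by edgeR with the depth block, and 5 were higher when adjusted over the list alone (camera adjusted p 1.3e-16, and 0.119 with the correlation estimated). CG31231 is lower in the authors' deposited tables of all S2 poly(A) comparisons, and these share the GFP library that holds its 786 reads, so its calls are 1 observation.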
